A study of Oryza sativa Japonica Group with 15 samples.

How the data were processed

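Single-cell Hi-C captures pairs of DNA segments that lay close together in the nucleus of 1 cell. It was applied to rice (Oryza sativa, japonica, cultivar Dongjin): 4 egg cells, 4 sperm cells, 3 unicellular zygotes taken 6 to 8 hours after pollination and 4 shoot cells from seedlings 12 days after germination, 15 libraries in all. Per the labels' protocols, each isolated cell was fixed with formaldehyde, its DNA was cut with the restriction enzyme DpnII and ligated, and the whole genome was amplified by multiple displacement, sheared by sonication and sequenced. No molecular identifiers were used, so read pairs are not independent molecules. The aligner, the contact caller and the genome build are not given in the sources used here.

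The deposited files list 1 read pair per line in the NCC contact format, with the chromosome, the read position, the restriction fragment and the strand of both ends. They hold positions and identifiers rather than a normalised value. All lines lay on the 12 nuclear chromosomes, and every group number occurred once, so no pair had a second mapping to choose from. The positions are on the unnamed build of the files. The gene table at hand belongs to another assembly, so gene density, gene lists, contacts within gene bodies and the genes chosen beforehand were not analysed here. A file that pairs chromosomes with chain letters was not used here.

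A contact was defined as 1 distinct pair of restriction fragments in a cell, placed at the fragments' midpoints. Contacts between chromosomes are called trans and those within a chromosome cis. A contact was called far when it was trans or spanned at least 20 kb, and long when it was cis and spanned over 2 Mb. Far cis contacts were divided at 200 kb, 2 Mb and 10 Mb. The decay slope is the exponent of contact density per possible pair of positions against separation, from 100 kb to 5 Mb, fitted by Poisson regression over 6 logarithmic classes. The trans share that random pairing would give was computed from the chromosomes' shares of far contact ends. The share of contacted fragments with 3 or more partner fragments was planned as a reading of copy number, since in 1 copy a fragment end can be ligated once.

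Centromeres were placed at megabase positions known for the rice reference genome, from 2.8 Mb on chromosome 9 to 19.4 Mb on chromosome 3. Their fit to the build of the files was not tested. Centromere contacts had an end within 1 Mb of these positions, and end contacts an end within 1 Mb of a chromosome end. In place of gene density quartiles, 500 kb bins were divided by distance from the centromere. Near bins were the closest quartile (up to 3.95 Mb) and distal bins the farthest (over 12.55 Mb). Expected trans counts came from the coverage of both ends. The chance range is the central 95% of values after 1000 circular shifts of each chromosome, within the same library. Arm alignment is the Spearman correlation, across trans contacts, of both ends' relative positions along their arms. Contacts across the centromere were set against the same separations placed at random.

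The labels name no plant, floret or seedling for any cell, so each group counts as 1 sample and no test between groups was made. Values are given per cell, with the mean and SD over cells. Exact (Clopper-Pearson) 95% intervals cover counting error only. Chromosome pairs were named by a rule fixed before the data were examined: the 3 highest and the 3 lowest by mean observed over expected in each group, among pairs with every cell on the same side of 1. Chance numbers of such pairs came from 1000 multinomial draws of the trans contacts of each cell with the expected shares. The matching rule for bins and genes could not be met at this depth and without a matching annotation.

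The alternatives tried were leaving out isolated contacts (no other contact with both ends within 1 Mb), thinning each cell to the shallowest, leaving out fragments with more than 4 partners and merging contacts to 1 per pair of 10 kb bins. Further ones were a 2 Mb window, an expectation without coverage, 1 Mb bins, a split at the median in place of quartiles, cis contacts over 2 Mb, at least 20 contacts per bin, and leaving out each cell or shoot cells 3 and 4. The design text counts fewer shoot cells than the 4 listed, which is why the last was run. Leaving out recurrent bins, 10 kb bins with far contacts in at least 5 of the 15 cells, was added after seeing the data.

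Measures were tested on simulated contacts. With the ends of egg 1 and sperm 2 paired at random 100 times, between 0% and 12% of values of a measure fell outside the range. The highest shares, in sperm 2, were 12% for centromere to end and 11% for near to near contacts. With 10% of contacts placed between centromeres, 99% of draws for egg 1 and 100% for sperm 2 were outside it. Separations drawn with an exponent of -1 gave a mean slope of -1.01 with an SD of 0.160 at 30 contacts. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.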

Results

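The series compares how chromosomes are folded in the rice egg, the sperm, the zygote formed from them and, as a somatic reference, cells of the shoot. The files held between 2236 read pairs (shoot cell 4) and 17291 read pairs (shoot cell 3) per cell. These came down to between 761 distinct contacts (sperm 4) and 4576 (egg 3). Far contacts, those between chromosomes or spanning at least 20 kb, numbered 401 to 558 in the 4 eggs, 130 to 390 in the 4 sperm, 222 to 401 in the 3 zygotes and 243 to 448 in the 4 shoot cells. Between 50.7% and 80.6% of the read pairs of a cell joined positions less than 1 kb apart. No plant of origin was given for any cell, so each group counts as 1 sample and differences between groups were not tested. Intervals cover counting error only.

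Zygotes and eggs had on average the largest trans share, the share of all contacts that joined different chromosomes. It was 27.1% ± 8.22 (SD, n = 3 cells) in zygotes, 22.3% ± 9.77 (SD, n = 4) in eggs, 15.6% ± 5.65 (SD, n = 4) in shoot cells and 13.2% ± 4.96 (SD, n = 4) in sperm. The ranges of cells overlapped: eggs spanned 10.1% to 34.0% and sperm 6.91% to 19.0%. Cells with many contacts tended to have a low share. It was 10.1% in egg 3 (4576 contacts), 10.3% in shoot cell 1 (3631) and 6.91% in sperm 1 (3446). Zygote 3 (785 contacts) had 35.4%, but sperm 4, with the fewest (761), had 13.9%. Zygotes had the fewest contacts on average (1002) and eggs the most (2327). Cell type and number of contacts therefore cannot be told apart as sources of the order of groups. Among far contacts, the trans share was 82.4% ± 2.23 in eggs, 83.4% ± 2.13 in zygotes, 80.4% ± 4.93 in shoot cells and 75.9% ± 10.1 in sperm. The sperm mean was 80.8% without sperm 1, which had 61.0% (interval 56.0% to 65.9%). Pairing the same ends at random would give 84.7% to 91.0% across the 15 cells. After merging contacts per pair of 10 kb bins, 9 cells lay below random pairing by more than the counting interval. The order of zygotes, eggs, shoot cells and sperm held with isolated contacts left out (16.3%, 13.4%, 7.02% and 6.29%) and without fragments of more than 4 partners (16.5%, 12.7%, 11.4% and 8.38%). It did not hold without contacts at recurrent 10 kb bins, described further on: the share of all contacts was then 13.64% in zygotes, 13.605% in shoot cells, 13.42% in eggs and 11.23% in sperm.

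**Figure D1:**
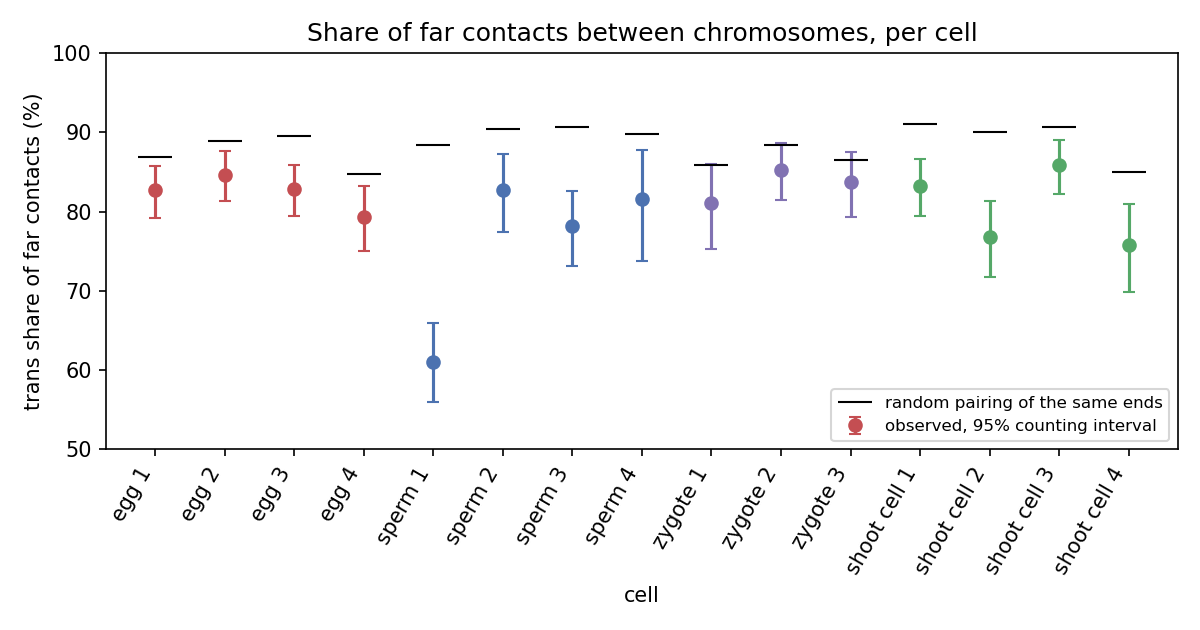
Trans share of far contacts (y axis, %) for each of the 15 cells (x axis), with exact 95% counting intervals; black lines mark the share that random pairing of the same ends would give. Sperm 1 has the lowest share at 61.0%, against 88.3% under random pairing.

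Within chromosomes, sperm had on average the lowest share of far cis contacts at 2 Mb or more. It was 42.3% ± 21.3 (SD, n = 4) in sperm, 54.6% ± 16.9 (SD, n = 4) in shoot cells, 59.9% ± 9.86 (SD, n = 4) in eggs and 61.7% ± 14.3 (SD, n = 3) in zygotes. Sperm cells ranged from 17.8% in sperm 1 to 67.4% in sperm 2, so the spread between sperm exceeded the differences between group means. With isolated contacts left out the sperm mean was 27.9% and the egg mean 49.5%. The egg mean was 47.4% without fragments of more than 4 partners and 44.4% without recurrent bins. Sperm had the lowest mean in each of these alternatives. The distance between eggs and sperm shrank without those fragments or bins, and grew with isolated contacts left out. With all contacts kept, shoot cells 1 and 2 each had 40%, whereas shoot cells 3 and 4 had 70.5% and 67.8%. Shoot cells 3 and 4 were registered apart from all other cells, so a difference between batches and spread between cells cannot be told apart. Without shoot cells 3 and 4 the shoot mean was therefore 40%, below that of sperm. In sperm 1 and sperm 3, 44.7% and 45.6% of far cis contacts spanned 200 kb to 2 Mb, against 8.33% in sperm 4. Contacts over 10 Mb made up 50.8% in shoot cell 3 and 4.17% in sperm 4. The mean decay slope was -0.68 ± 0.31 in eggs, -0.73 ± 0.81 in sperm, -0.74 ± 0.43 in zygotes and -0.53 ± 0.25 in shoot cells. The steepest slope was -1.53 (SE 0.098, 107 contacts) in sperm 1, without which the sperm mean was -0.463. The mean was -0.446 in zygotes without recurrent bins, and in shoot cells -0.937 with isolated contacts left out and -0.207 with thinned cells. The slope of 0.36 in sperm 4 rested on 7 contacts, and the sperm mean without sperm 4 was -1.09.

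**Figure D2:**
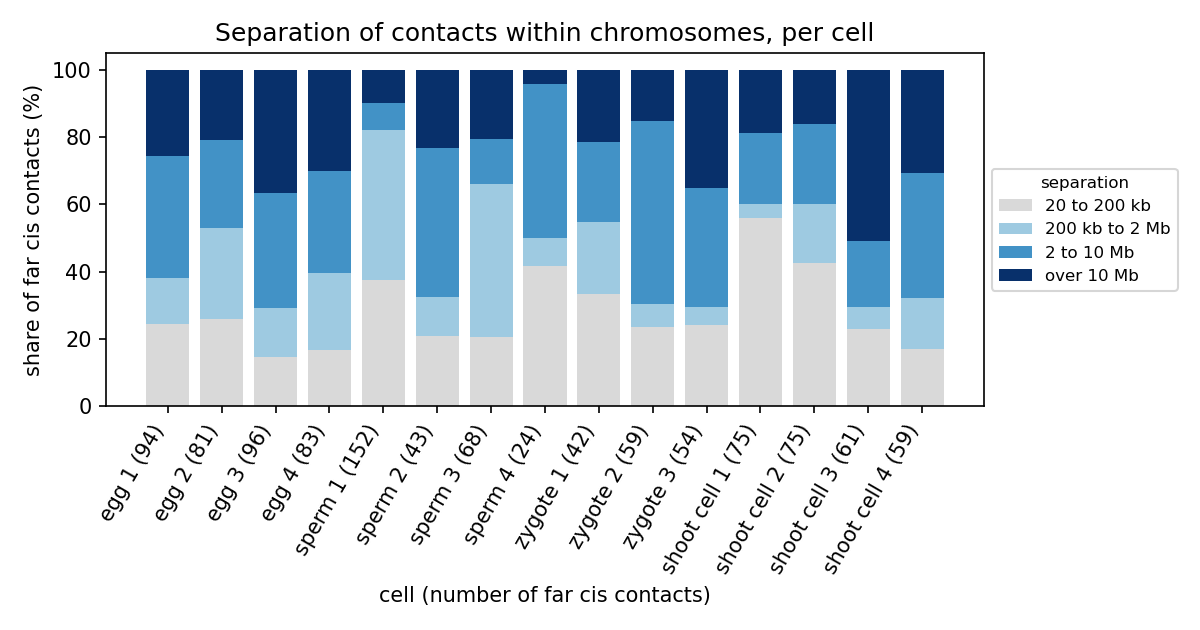
Share of far cis contacts (y axis, %) in 4 classes of separation for each of the 15 cells (x axis, with the number of far cis contacts in parentheses). Contacts at 2 Mb or more range from 17.8% in sperm 1 to 70.8% in egg 3.

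Clustering of centromeres was asked of trans contacts with both ends within 1 Mb of a centromere. Eggs had 6 such contacts against 2.23 expected, a ratio of 2.69 with a chance range of 0 to 2.12. Shoot cells had 10 against 5.64 expected (ratio 1.77, chance range 0 to 2.51), zygotes 1 against 0.557, and sperm 0 against 0.781. Shoot cell 2 gave 7 of the 10, and the ratio without it was 1.01; the zygote contact was in zygote 1, without which the ratio was 0. The egg value lay inside the range without egg 4 (1.93) or egg 2 (2.26), with isolated contacts (3.83) or recurrent bins (2.04) left out, with a 2 Mb window (0.996) and with an expectation without coverage (0.830), and above it with thinned cells, with merged contacts and without fragments of more than 4 partners.

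Contacts between chromosome ends were above the chance range in sperm and in shoot cells. Sperm had 8 against 2.29 expected (ratio 3.49, chance range 0 to 3.11) and shoot cells 13 against 4.59 (ratio 2.83, chance range 0 to 2.38). The ratio was 1.76 in eggs and 1.03 in zygotes, both inside their ranges. It was 1.10 without egg 4, which had 2 contacts against 0.117 expected, 2.31 without egg 3 and 0.553 without zygote 1. Of the contacts in sperm and shoot cells, 5 came from sperm 1 and 6 from shoot cell 1. Without those cells the ratios were 1.65 and 1.77, inside the range, as was the sperm ratio of 3.40 without sperm 4, whereas they were above it at 6.33 without sperm 2, 4.29 without shoot cell 3, 6.10 without shoot cells 3 and 4 and, in zygotes, 6.43 without zygote 2. The ratios in sperm and shoot cells were inside the range with contacts merged per 10 kb pair (2.16 and 1.74), a 2 Mb window (1.16 and 1.38), an expectation without coverage (2.37 and 2.66) and recurrent bins left out (3.16 and 2.45). Leaving out fragments with more than 4 partners turned the sperm ratio to 0.888 but gave 5.11 in shoot cells and 2.95 in eggs, both above the range, and shoot cells with isolated contacts left out (6.67) and thinned sperm (5.97) were also above it.

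Centromeres met chromosome ends in 0 sperm contacts against 3.28 expected, below the chance range of 0.185 to 2.19. Leaving out any sperm cell widened that range to include 0, and a 2 Mb window gave a ratio of 0.990. The ratio was 1.01 in eggs, 0.469 in zygotes and 0.601 in shoot cells, each inside the range. Without single cells it was 0.506 (egg 1) and 1.52 (egg 2) in eggs and 0 (zygote 1) and 1.60 (zygote 2) in zygotes.

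**Figure D3:**
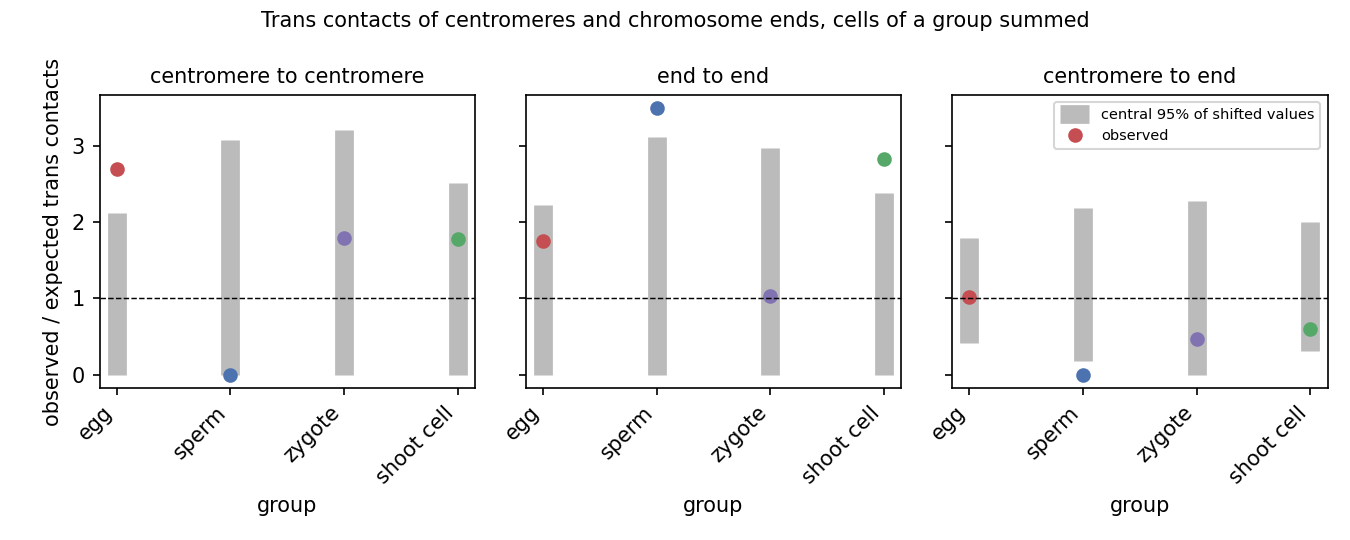
Observed over expected trans contacts (y axis) between centromeres, between chromosome ends and between both, with the cells of each group (x axis) summed; grey bars are the central 95% of values after circular shifts and the dashed line is 1. Sperm (3.49) and shoot cells (2.83) lie above the bar for ends, and eggs (2.69) for centromeres.

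A polar arrangement of chromosome arms would align trans contacts by position along the arm. Alignment was 0.093 in shoot cells, above the chance range of -0.093 to 0.078, with 0.238 in shoot cell 2 and 0.044 in the mean without it. It was inside the range with isolated contacts (0.0947) or fragments of more than 4 partners (0.0701) left out, with merged contacts (0.0520) and without shoot cells 3 and 4 (0.0993), and above it with thinned cells and without recurrent bins. Alignment was -0.016 in eggs, -0.0067 in sperm and -0.112 in zygotes, inside the ranges. The sperm mean was -0.0601 without sperm 1 and 0.0588 without sperm 3. The zygote mean was below its range without zygote 1 (-0.144), with isolated contacts (-0.248) or fragments of more than 4 partners (-0.202) left out and with thinned cells (-0.141), but zygote 3 had -0.242, outside its own range, and the mean was -0.0464 without it and -0.0610 with merged contacts, both inside. Without recurrent bins alignment turned to 0.018 in zygotes and to 0.0999 in eggs, the latter above its range. Cis contacts that crossed the centromere occurred at 1.09 times the expected number in eggs (counting interval 0.954 to 1.22), 0.806 in sperm (0.588 to 1.05), 0.900 in zygotes (0.675 to 1.14) and 0.883 in shoot cells (0.715 to 1.06). With isolated contacts left out, the ratio lay below 1 by more than the interval in sperm (0.456), zygotes (0.555) and shoot cells (0.769). The contacts kept there all have a neighbour, so they are not independent and that interval is too narrow to decide. Without recurrent bins the ratio was below 1 by more than the interval in sperm (0.716), whereas it was 1.11 in zygotes.

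Segregation of chromatin was read from bins near to and distal from centromeres, since gene density was not used here. Near bins met near bins at 1.13 times expectation in eggs, 0.936 in sperm, 0.828 in zygotes and 1.09 in shoot cells, all inside the chance range. The value lay above the range in shoot cells without shoot cell 1 (1.34) and in eggs with an expectation without coverage (1.75, chance range 0.542 to 1.57). Distal bins met distal bins at 1.33 times expectation in eggs, above the range of 0.791 to 1.22. The ratio was 1.04 in sperm, 0.831 in zygotes and 0.968 in shoot cells, and near to distal contacts ranged from 0.914 in shoot cells to 1.13 in zygotes, all inside their ranges. Egg 3 alone had 1.83, and the value without it was 1.26, inside the range. The egg value was also inside the range with isolated contacts left out (1.30), thinned cells (1.23) and recurrent bins left out (1.19), and turned to 0.935 with an expectation without coverage and to 0.964 with a split at the median. Over all these trans measures, 6 of the 28 group values lay outside their 95% ranges, where the nominal rate gives 1.4. That number is only a guide. The values share contacts, and with the ends of egg 1 and sperm 2 paired at random between 0% and 12% of values of a measure fell outside. Those rates are for single cells with fewer shifts. The rate for values over the cells of a group was not simulated. None of those 6 values stayed outside under every alternative tried (0 values). Leaving out contacts or cells also widens the range, so a return inside it need not mean a weaker ratio. With isolated contacts left out, the egg centromere ratio rose to 3.83, with an upper limit of 3.87. The sperm end ratio without sperm 4 was 3.40, with an upper limit of 3.46. Other ratios did move towards 1, such as that of egg centromeres with a 2 Mb window (0.996). With the 1 Mb window, the upper limits of the chance ranges for centromeres and for ends lay between 2.12 and 3.21. A smaller excess was thus not detectable with that window at this depth. A 2 Mb window gave lower limits, such as 1.48 for centromeres in eggs and 1.87 in sperm.

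Chromosomes 4 and 11 met more often than expected in every egg, sperm and zygote. The mean ratio was 1.96 ± 0.38 in sperm, 1.62 ± 0.41 in eggs and 1.23 ± 0.30 in zygotes, and shoot cells gave 0.564 ± 0.51. The lowest zygote had 1.01. With isolated contacts left out, the mean turned to 0.412 in zygotes and was 6.17 in eggs and 5.85 in sperm; merging per 10 kb pair gave 1.16 in eggs and 1.45 in sperm, and leaving out recurrent bins 2.45 in zygotes. In eggs chromosomes 1 and 10 (1.498 ± 0.44) and 4 and 12 (1.34 ± 0.14) were also above 1 in every cell, though 4 and 12 fell to 0.619 without recurrent bins. In sperm these were chromosomes 1 and 8 (1.81 ± 1.06) and 1 and 7 (1.58 ± 0.61), and in zygotes 2 and 11 (1.58 ± 0.34) and 1 and 12 (1.32 ± 0.19). The last fell to 0.547 without recurrent bins, and 2 and 11 to 0.965 without fragments of more than 4 partners. With isolated contacts left out, the egg means of 1 and 10 and of 4 and 12 were 0.987 and 0.852, and with thinned cells the sperm mean of 1 and 7 was 0.845. Chromosomes 5 and 8 met less than expected in every sperm (0.493 ± 0.35), zygote (0.142 ± 0.25) and shoot cell (0.229 ± 0.46), but eggs gave 1.23 ± 0.58. The zygotes had 1 such contact against 2.89 expected. Over the alternatives, left-out cells included, these means ranged from 0 to 0.915 in sperm, 0 to 0.388 in zygotes and 0 to 0.459 in shoot cells. The other lowest pairs, with their ranges over the alternatives, were 10 and 11 (0.295, 0 to 0.393), 7 and 11 (0.389, 0 to 0.519) and 8 and 9 (0.489, 0.138 to 0.594) in eggs, and 3 and 6 (0.414, 0 to 1.19) and 1 and 9 (0.498, 0.251 to 0.800) in sperm. In zygotes they were 6 and 10 (0.114, 0 to 0.214) and 4 and 7 (0.150, 0 to 0.261), and in shoot cells 4 and 6 (0.162, 0 to 0.265) and 8 and 9 (0.258, 0 to 0.368). Single cells moved several of these by over 1.5 times. The 3 zygote pairs were at 0 without zygote 2, and in shoot cells 5 and 8 were at 0 without shoot cell 2, 8 and 9 at 0.0749 without shoot cell 3 and 4 and 6 at 0.0829 without shoot cell 1. In eggs 10 and 11 were at 0.176 without egg 2 and 7 and 11 at 0.212 without egg 1. Of the 66 pairs, 3 were above and 10 below in every egg, 5 and 9 in sperm, 4 and 12 in zygotes, and 0 and 8 in shoot cells. When the contacts of each cell were drawn 1000 times with the expected shares, a comparison chosen after the counts were seen, the mean numbers above and below were 3.16 and 5.20 in eggs, 2.95 and 5.59 in sperm, 6.35 and 10.7 in zygotes, and 2.79 and 5.80 in shoot cells. The counts lay within the central 95% of draws except for the 10 pairs below in eggs (2 to 9), whose number was 6 without recurrent bins and 11 with merged contacts. The draws treat contacts as independent, although contacts can share a fragment. Expected shares come from the product of the chromosomes' trans contact ends and do not keep each chromosome's total. They tend to be too low for pairs of chromosomes with many contacts and too high for pairs with few. The draws use the same shares and cannot show this, so pairs above or below 1 may partly reflect it.

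Haploid and diploid cells were not separated by the number of partners per fragment, but the measure could not read copy number here. In 1 copy of the genome a fragment end can be ligated once, so no fragment should have 3 or more partners. Eggs and sperm nevertheless had such fragments at shares close to those of zygotes and shoot cells. Fragments with 3 or more partners made up 14.5% ± 2.38 (SD, n = 4) in eggs and 13.3% ± 5.57 (SD, n = 4) in sperm, which are haploid. The share was 13.9% ± 4.13 (SD, n = 3) in zygotes and 12.8% ± 6.56 (SD, n = 4) in shoot cells, which are diploid. With every cell thinned to the same number of contacts, the mean was 6.42% in eggs, 6.42% in sperm, 11.3% in zygotes and 3.86% in shoot cells. The comparison of compartment values was not possible: of 752 bins of 500 kb, 1 had at least 10 contacts in every zygote and egg, and 0 did so in the comparisons of egg with sperm, zygote with sperm and shoot cell with egg.

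Far contacts gathered at a few places that were the same in many cells. Of 37272 bins of 10 kb, 95 had far contacts in at least 5 of the 15 cells, against a mean of 0.020 when the contacts of each cell were shifted along the chromosomes. On the coordinates of the files, whose build is not given, chromosome 12 from 13340001 to 13420000 took part in 486 far contacts over all 15 cells. Chromosome 9 from 4670001 to 4730000 and chromosome 12 from 20620001 to 20670000 each did so in 14 cells, and chromosome 1 from 33510001 to 33590000 in 13 cells. With the bins taken from the other cells only, the share of far contacts with an end in such a bin was 57.2% ± 8.12 (SD, n = 3) in zygotes, 44.1% ± 29.3 (SD, n = 4) in eggs, 16.8% ± 15.5 (SD, n = 4) in sperm and 15.9% ± 11.1 (SD, n = 4) in shoot cells. Egg 3 had 3.23% (interval 1.92% to 5.05%), whereas the other eggs ranged up to 72.8%. The egg mean was 57.7% without egg 3, above that of zygotes, and the sperm mean 9.51% without sperm 4, which had 38.5%, below that of shoot cells.

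**Figure D4:**
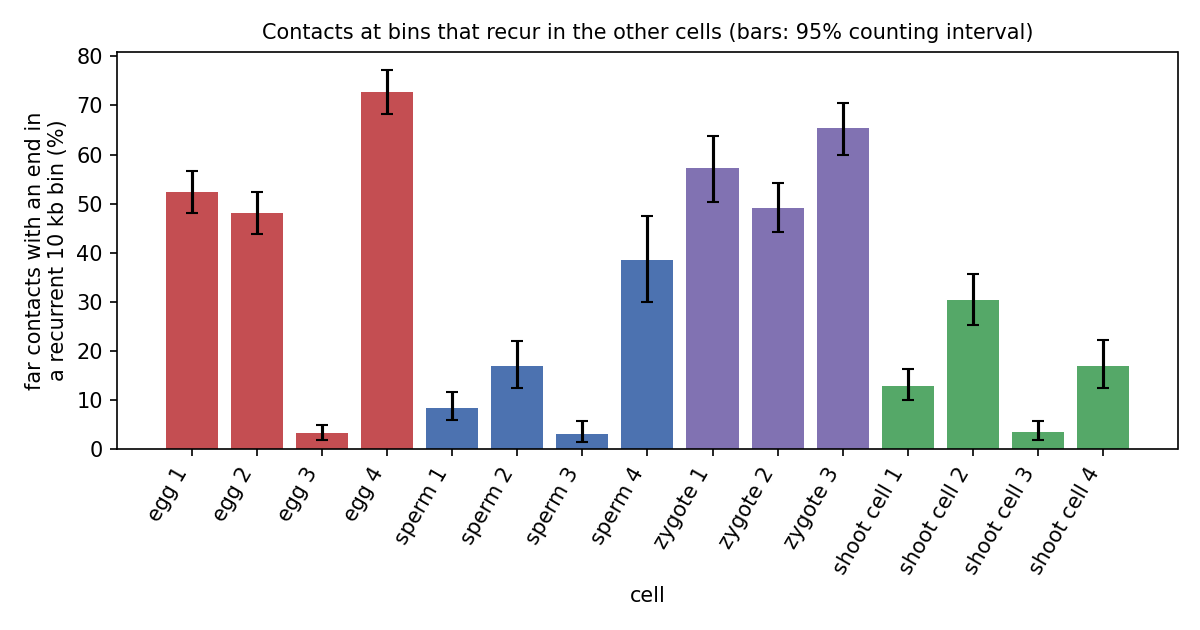
Share of far contacts with an end in a recurrent 10 kb bin (y axis, %), with the bins defined from the other 14 cells, for each of the 15 cells (x axis); error bars are exact 95% counting intervals. Egg 3 (3.23%) and sperm 3 (3.22%) have the lowest shares and egg 4 (72.8%) the highest.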

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

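Leaving out recurrent bins was chosen after seeing the data. Of 941 values under alternatives to 101 reported values, 754 kept their side of the chance range, moved by less than 1 SD between cells or, for counts, stayed within 1.5 times, but 96 of these moved by over 1.5 times, to 0 or to the other sign. The cause of each change below was not tested, except that leaving out cells lets more chromosome pairs lie on 1 side. Keeping ambiguous contacts changed nothing to compute, because no read pair had a second mapping, and gene lists were not run. No paired analysis was possible because cells of different types share only a number and no test between groups was made. Expected contacts per group were 0.557 to 9.99 for centromeres and ends, 2.89 to 56.0 for named chromosome pairs and 30.1 to 234 for near and distal bins, and depth ruled out compartment values. Ratios are observed over expected, and values are in the order given. With isolated contacts left out, the trans share of all contacts was 13.4% in eggs, 6.29% in sperm, 16.3% in zygotes and 7.02% in shoot cells. That of far contacts was 73.6%, 63.7%, 77.5% and 68.5% in eggs, sperm, zygotes and shoot cells. Far cis contacts at 2 Mb or more made up 49.5% in eggs and 27.9% in sperm, and the slope was -0.937 in shoot cells. The centromere ratio was 3.83 in eggs, the end ratio 6.67 in sperm, inside its range, and 6.67 in shoot cells, above it, and centromere to end 0 in sperm and shoot cells. Near to near was 0.635 in sperm and 0.645 in zygotes, and alignment -0.248, below its range, in zygotes and 0.0947 in shoot cells. Crossing the centromere was 0.456, 0.555 and 0.769 in sperm, zygotes and shoot cells, below 1 beyond an interval that treats these neighbouring contacts as independent. Pairs above in every cell numbered 0 in eggs, 2 in sperm and 2 in zygotes, and pairs below 19, 20 and 18 in sperm, zygotes and shoot cells. Chromosomes 1 and 10 (0.987) and 4 and 12 (0.852) in eggs and 4 and 11 in zygotes (0.412) changed side. With merged contacts, the trans share of all contacts was 33.0%, 20.8%, 37.5% and 23.6% in eggs, sperm, zygotes and shoot cells, and fragments with 3 or more partners 4.85%, 2.39%, 5.54% and 2.24%. End ratios were 2.16 in sperm and 1.74 in shoot cells, near to near 1.08 in sperm and alignment 0.0520 in shoot cells. Pairs above numbered 6, 3 and 4 in eggs, sperm and shoot cells, and pairs below 5 in sperm. Without fragments of more than 4 partners, the trans share was 12.7%, 8.38% and 16.5% of all contacts in eggs, sperm and zygotes and 76.0% and 77.5% of far contacts in eggs and zygotes. Fragments with 3 or more partners made up 7.55%, 7.09% and 7.58% in eggs, sperm and zygotes, and far cis contacts at 2 Mb or more 47.4% in eggs. End ratios were 2.95, above its range, in eggs, 5.11, above its range, in shoot cells and, on the other side of 1, 0.888 in sperm. Centromere to end was 0 in sperm, near to near 1.01 in sperm and 0.664 in zygotes, alignment -0.202, below its range, in zygotes and 0.0701 in shoot cells, and crossing 0.947 in eggs. Pairs below numbered 19 in zygotes and pairs above 2 in shoot cells, and chromosomes 2 and 11 in zygotes changed side (0.965). Without recurrent bins, the trans share was 13.42% of all contacts in eggs and, in zygotes, 13.64% of all and 79.6% of far contacts. In eggs fragments with 3 or more partners made up 12.2% and far cis contacts at 2 Mb or more 44.4%. The centromere ratio was 2.04 in eggs, end ratios 3.16 in sperm and 2.45 in shoot cells, centromere to end 0 in sperm, and near to near 1.25 in eggs and 1.11 in zygotes. Alignment changed sign in eggs (0.0999) and was 0.0182 in zygotes, and crossing was 0.716 in sperm and 1.11 in zygotes. Pairs below numbered 6 in eggs and pairs above 2 in sperm and 1 in shoot cells. Chromosomes 4 and 12 in eggs (0.619) and 1 and 12 in zygotes (0.547) changed side. With thinned cells, the trans share of far contacts was 85.2% in eggs, fragments with 3 or more partners made up 6.42% in eggs and in sperm and 3.86% in shoot cells, and the slope was -0.207 in shoot cells. The end ratio was 2.05 in shoot cells and 5.97, above its range, in sperm, centromere to end 0 in sperm, near to near 1.07 in sperm, alignment -0.141, below its range, in zygotes and crossing 0.933 in sperm. Pairs above numbered 1 in sperm and 1 in shoot cells and pairs below 3 in sperm, where chromosomes 1 and 7 (0.845) and 3 and 6 (1.19) changed side. A 2 Mb window gave centromere ratios of 0.996 in eggs, a change of side, and 0.921 in sperm. It gave end ratios of 1.16 in sperm and 1.38 in shoot cells, and centromere to end 0.990 in sperm. An expectation without coverage turned the egg centromere ratio to 0.830 and distal to distal to 0.935. It gave end ratios of 2.37 in sperm and 2.66 in shoot cells, and near to near 1.75, above its range, in eggs and 1.12 in zygotes. Cis contacts over 2 Mb gave near to near 1.53, 1.06 and 0.391 in sperm, zygotes and shoot cells. A split at the median gave near to near 0.982 in zygotes and distal to distal 0.964 in eggs, a change of side. Without shoot cells 3 and 4, the end ratio was 6.10, above its range, alignment was 0.0993, and 10 pairs lay above and 22 below. At least 20 contacts per bin left 0 bins for zygote against egg. Leaving out 1 cell changed a call for egg 2 (2.26) and egg 4 (1.93) in centromere ratios. It did so for sperm 1 (1.65), sperm 4 (3.40), zygote 2 (6.43) and shoot cell 1 (1.77) in end ratios, and for each sperm cell (0) in centromere to end. It did so for shoot cell 1 (1.34) in near to near, egg 3 (1.26) in distal to distal, and zygote 1 (-0.144) and shoot cell 2 (0.0441) in alignment. Leaving out 1 cell at a time, centromere ratios ranged from 1.93 to 3.98 in eggs, and end ratios from 1.65 to 6.33 in sperm, 0.553 to 6.43 in zygotes and 1.77 to 4.29 in shoot cells. Centromere to end stayed at 0 in sperm, near to near ranged from 0.961 to 1.34 in shoot cells, and alignment from -0.145 to -0.0464 in zygotes and 0.0441 to 0.136 in shoot cells. Pairs above ranged from 5 to 7, 6 to 8, 7 to 11 and 1 to 4 in eggs, sperm, zygotes and shoot cells, and pairs below from 12 to 16, 13 to 17, 20 to 29 and 10 to 17.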

Other observations

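All tests on the number of short contacts and on random ligation were chosen after the values they use had been seen, as were the strand expectation per fragment and the count of end contacts at recurrent bins. The tests of read starts, of strand agreement and of contacts between ends after merging or without 1 cell were set before their results were seen. In 33 sets of 4 values, each a measure in eggs, sperm or shoot cells, Dixon's ratio of gap to range passed its 95% critical value in 0 sets. Chance gives about 1.65 such sets, and the 3 zygotes were not tested in this way. That does not mean that no cell stood out in any measure. The end to end ratio was 9.59 in shoot cell 1, against 1.61 to 2.11 in the other shoot cells.

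With recurrent bins left out, an alternative chosen after seeing the data, 3 egg values left their chance ranges, the last 2 of them narrowly, and 2 came back inside. Arm alignment in eggs was 0.0999 (chance range -0.125 to 0.0881), near bins met near bins at 1.250 times expectation (chance range 0.775 to 1.248), and near bins met distal bins at 0.818 times (chance range 0.821 to 1.17). In the unfiltered contacts these were -0.016, 1.13 and 0.920, inside their ranges. The values that came back were contacts between centromeres, at 2.04 (chance range 0 to 2.61) in place of 2.69, and between distal bins, at 1.19 (chance range 0.720 to 1.28) in place of 1.33.

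The gathering of far contacts at the same 10 kb bins may come from DNA that is continuous in the cell and that the reference places at separate positions. The same fragment pair was found in at least 2 cells in 200 cases, and pairs of cells that shared one had the same leading strand combination in 77.6% of comparisons, where independent ligation gives 25%. In the 327 comparisons where each fragment's own strand use could be allowed for, agreement was 76.1% against 45% expected, and with 1 comparison per fragment pair it was 77.5% (counting interval 71.1% to 83.1%), an interval that includes the mark set beforehand. Reads carried over between libraries after shearing are argued against, since 2% of the shared fragment pairs had the same read starts in 2 cells. DNA passed between cells before shearing would give other read starts, so that test cannot exclude it. Short contacts in these bins exceeded 5 times their genome share in 12 cells (5.01 in sperm 1), but not in egg 3 (2.79), shoot cell 3 (1.92) and sperm 3 (0.837). That goes against ordinary nuclear copy number only if amplification was even, which was not measured. A nuclear repeat of fixed copy number stays open: the share of short contacts differed 105-fold between egg 4 and sperm 3, which had 2 such contacts, and 44.6-fold between egg 4 and shoot cell 3, which passed the bound first set against it, but uneven amplification of single cells was not measured and that bound was given up; mitochondrial or plastid DNA assigned to nuclear insertions was not tested, since no organelle sequence was used here, and a difference in organelle content between cell types also stays open.

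The excess of contacts between chromosome ends in sperm and shoot cells could be the yield of few ligations in few cells, but the alternatives went both ways. With several fragment pairs from 1 ligation merged per pair of 10 kb bins, 0 groups stayed above the chance range, and the ratios fell from 3.49 to 2.16 in sperm and from 2.83 to 1.74 in shoot cells. Likewise, in 0 groups did the ratio stay above the range for every choice of the cell left out. It was inside at 1.65 without sperm 1, at 1.77 without shoot cell 1 and, barely, at 3.40 without sperm 4 (upper limit 3.46). It was above at 6.33 without sperm 2 and at 4.29 without shoot cell 3. The shoot ratio was also above the range at 5.11 without fragments of more than 4 partners and at 6.67 without isolated contacts, and that of thinned sperm at 5.97. Recurrent bins near chromosome ends are argued against: 1 of the 95 bins lay within 1 Mb of an end, and of the 21 contacts between ends in sperm and shoot cells 0 had an end in a recurrent bin, although the outcome first set for this explanation, no group above the range without these bins, was met (3.16 and 2.45), and the count of contacts took its place after the values were seen. Clustering of telomeres in these cell types stays open.

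Far contacts were mostly between chromosomes, as random ligation would also give. Random ligation of all far contacts is argued against by 9 cells, whose trans share after merging lay below random pairing by more than the counting interval. The gap was 21.9 percentage points in sperm 1, 16.1 in shoot cell 2 and between 3.26 (egg 3) and 8.61 (sperm 3) in the other 7. In the other 6 cells the interval included random pairing, although the gap of 5.65 points in zygote 1 exceeded that of egg 3. Where the gap was small, in cells of either kind, trans contacts may hold a large share of random ligation. A difference between cell types in how far chromosomes intermingle was not tested.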
